A study of Rattus norvegicus with 9 samples.

How the data were processed

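Ligaments of 27 male rats were snap frozen, and RNA of 3 ligaments per pool was labelled with biotin and hybridised to Affymetrix 3' expression arrays, per the labels' protocols. The deposited log2 values are per probe set, already summarised and normalized between arrays by the authors. The software, version and settings are not given in the sources used here. Per the file headers, the authors' deposited table also holds log2 differences and fold changes of each injured day against intact, and pairwise p-values. It further holds p-values, q-values and Benjamini-Hochberg values over the 3 groups. It repeats the 9 columns of log2 values exactly. The pairwise p-values of that table were used only as an alternative.

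Samples were grouped by their labels into intact, injured day 3 and injured day 7, with 3 pools each. Pools of different groups come from different rats, and the model has no block. Same-numbered intact and day 7 pools nevertheless deviated together from their group means (correlations of 0.118, 0.106 and 0.131), each pool most with its own number. These correlations are small and are weak grounds for a pairing. A replicate block is given beside that comparison where it changes a call. It was fitted over all 9 arrays, day 3 pools included, so it does not adjust for a pairing of intact and day 7 pools alone. Of 31099 probe sets, 57 controls were left out, 20826 had 1 gene symbol, 436 had several and 9780 were not in the annotation table. Each of 14217 genes was represented by the probe set with the highest mean over all 9 arrays; 4525 genes had more than 1. Of these symbols 14204 matched the reference gene table of assembly GRCr8, which was used for names only. Exactly tied values in all 3 pools of a group occurred in 34 genes for intact, 60 for day 3 and 66 for day 7.

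One group-means model over all 9 arrays was fitted with limma 3.58.1 in R 4.3.3 (6 residual and 2.86 prior degrees of freedom). Its moderated test was applied to day 3 vs intact, day 7 vs intact and day 7 vs day 3, with Benjamini-Hochberg adjustment over all genes and a call at an adjusted p below 0.05. Gene lists (35, fixed before the data were examined, 684 of 786 members measured) were tested with camera at its preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. With an estimated correlation camera also uses only the 6 residual degrees of freedom, which lowers its power. A call lost under that setting therefore does not measure the correlation between genes alone. Controls shared by comparisons were treated with 50 simulations of unchanged groups. The control transcripts were compared with exact permutation tests.

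Genes to be named were set before the data were examined: 19 fixed genes, the 6 largest increases and decreases among called genes whose pools did not overlap, and up to 4 called members and 1 uncalled member of each described list. After the results were seen this was narrowed to the first 2 called members by size of change and the uncalled member of each called list, taken in that order and not by stability. Each gene so chosen is reported, together with the single pools whose removal ended its call.

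The procedure was tested on simulated data with 200 changed genes of 14217 in each comparison. Of 100 genes changed by 0.5 on the log2 scale, 68, 65 and 68 were recovered in the order of comparisons above, and of 100 changed by 1, 96, 98 and 96. Of the unchanged genes 5, 7 and 11 were called, and of 34 unshifted lists 0. These simulated genes were independent, so the list result does not cover correlated genes. In the data far larger shares of genes were called (48.7%, 45.6% and 17.0%), and the adjusted threshold depends on the share that changed. The recovered and false calls therefore do not give the rates in these data.

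Alternatives planned beforehand were filters at the 25th percentile and the median, quantile, median, 75th percentile and cyclic loess scaling, the mean of probe sets, every probe set, an intensity trend, array weights, only the 6 arrays compared, a replicate block, a 2-fold minimum and leaving out each pool. Those added after seeing the data were covariates of the muscle and cartilage list means, leaving out genes with tied values, spike-in scaling and the authors' p-values. The 2-fold minimum, spike-in scaling and the authors' p-values were applied to counts only, and every probe set to counts and lists. Ranges said to be over all alternatives therefore hold only the settings run for that gene or list. No raw probe intensities were used here.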

Results

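Gene expression was measured in the medial collateral ligament (MCL), a knee ligament, of male Wistar rats. Groups were intact ligaments, ligaments collected 3 days after surgical transection and ligaments collected 7 days after it. Each group held 3 pools of 3 ligaments, drawn from 9 rats, and each of the 9 pools was hybridised to 1 Affymetrix array. Array medians lay between 7.23 and 7.26 on the log2 scale. The number of arrays limits the precision of each value. The first principal component held 74.6% of the variance and placed the 3 intact pools between 45.37 and 61.05, against -35.98 to -19.16 for the 6 injured pools. The second held 11.6% and placed the day 3 pools between -19.46 and -13.61 and the day 7 pools between 12.70 and 22.42. Values given after a gene are log2 differences ± the standard error of limma's fit, with n = 3 pools per group.

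The first comparison asked how the ligament 3 days after transection differed from the intact ligament. Mmp13, which encodes a collagen-cleaving metalloproteinase, rose by 4.26 ± 0.77, and by 3.13 without intact pool 2, where it lay below Il1rl1 (4.00). All 45 measured genes of the mitotic cell cycle and all 21 measured macrophage markers rose. Among the 34 measured skeletal muscle markers 33 fell, as did 15 of 19 adipocyte markers and the ligament markers Fibin, Chad, Tnmd and Scx. With an estimated correlation the mitotic, macrophage, muscle and adipocyte lists were at adjusted p = 0.359, 0.359, 0.414 and 0.359. The transcripts of the main fibrillar collagens, Col1a1 (-0.06 ± 0.05, adjusted p = 0.301), Col1a2 (-0.05 ± 0.05, adjusted p = 0.458) and Col3a1 (0.12 ± 0.05, adjusted p = 0.0517), did not pass the test. Their levels lay near the top of the arrays' range, where 50 probe sets of each day 3 array were above 14.

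Of 14217 genes, 6927 were called at an adjusted p below 0.05 (limma with Benjamini-Hochberg adjustment), 4320 higher and 2607 lower, and 1253 of them differed at least 2-fold, 648 higher and 605 lower. The share of higher calls was 62.4%, 52.0% with cyclic loess between arrays, and 97.0% (12358 higher, 388 lower) with arrays scaled to the poly-A spike-ins. In 8033 genes (56.5%) the 3 pools of one group all lay beyond the 3 pools of the other, where chance gives 10%. After Mmp13, the largest increases were those of Il1rl1 (4.19 ± 0.39), a receptor of interleukin 33, of the potassium channel gene Kcnj15 (3.88 ± 0.52), of Steap1 (3.74 ± 0.25), of the neurofilament gene Nefh (3.71 ± 0.55) and of Shcbp1 (3.68 ± 0.20). Without intact pool 1 Mmp13 was at 4.89, Kcnj15 at 4.64 and Nefh at 4.37, and Nefh was at 3.09 without intact pool 3. The largest decreases were in Ckmt2 (-5.82 ± 1.00), Hjv (-5.68 ± 0.92), Ckm (-5.67 ± 1.48), Cox8b (-5.60 ± 0.81), Myl2 (-5.59 ± 0.88) and Myh7 (-5.59 ± 1.05), which are expressed in muscle. In that order these 6 were at -4.98, -4.95, -4.34, -4.91, -4.85 and -4.58 without day 3 pool 2, and at -6.64, -6.37, -6.81, -6.30, -6.40 and -6.68 without day 3 pool 3.

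Mitotic genes were higher as a group at day 3: 45 of 45 measured members rose, 0 fell and 0 did not pass the test (median 2.40). Mitotic cell cycle had a camera adjusted p of 3.21e-22, and adjusted p = 0.359 with an estimated correlation. Ccna2, a cyclin, rose by 3.41 ± 0.30, the spindle checkpoint kinase gene Ttk by 3.20 ± 0.22 and the proliferation marker Mki67 by 3.08 ± 0.28. Of the macrophage markers 21 of 21 measured members rose, 0 fell and 0 did not pass the test (median 1.46), among them Arg1 (2.52 ± 0.16), Mpeg1 (2.48 ± 0.18) and Cd68 (2.07 ± 0.12). Macrophage markers had a camera adjusted p of 8.22e-12, and adjusted p = 0.359 with an estimated correlation. For antigen presentation by MHC class II, 10 of 10 measured members rose, 0 fell and 0 did not pass the test (median 0.93), with RT1-DMa at 1.64 ± 0.10 and RT1-DMb at 1.58 ± 0.08. Antigen presentation by MHC class II had a camera adjusted p of 9.21e-05, and adjusted p = 0.359 with an estimated correlation. Among T and natural killer cell markers 10 of 17 measured members rose, 0 fell and 7 did not pass the test (median 0.40). T and natural killer cell markers had a camera adjusted p of 0.00369, and adjusted p = 0.359 with an estimated correlation. Cd3g rose by 1.35 ± 0.12 and Cd4 by 1.26 ± 0.13, while Zap70 was at 0.15 ± 0.07 (adjusted p = 0.0886). Only 1 of the 17 members lay above the median gene in the mean of the intact pools. The median of this list was 0.25 without intact pool 2. All counts of these 4 lists were the same adjusted over the list alone.

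In the inflammatory list 19 of 39 measured members rose, 2 fell and 18 did not pass the test, and 20 rose and 2 fell adjusted over the list alone (median 0.30). Inflammatory cytokines, chemokines and mediators had a camera adjusted p of 0.0482, and adjusted p = 0.414 with an estimated correlation. Il6 rose by 2.52 ± 0.15, the chemokine gene Ccl7 by 2.11 ± 0.10 and Il1b by 1.06 ± 0.19, while Cxcl12 was at -0.02 ± 0.13 (adjusted p = 0.92). The call of this list ended without day 3 pools 1 or 3, day 7 pool 1, or intact pool 1 (adjusted p 0.0513 to 0.0747), and with the mean of probe sets or the cartilage covariate (adjusted p 0.0558 to 0.0689). Complement had 9 higher members of 15 and none lower (median 0.63), the same adjusted over the list alone, with C3 at 3.25 ± 0.33 and Cfi at 2.53 ± 0.52, which was 3.26 without intact pool 1, and with Serping1 at -0.13 ± 0.06 (adjusted p = 0.0872). Complement had a camera adjusted p of 0.0186, and adjusted p = 0.414 with an estimated correlation. In the secretory pathway and unfolded protein response 20 of 29 measured members rose, 4 fell and 5 did not pass the test (median 0.46), the same adjusted over the list alone. Secretory pathway and unfolded protein response had a camera adjusted p of 0.00391, and adjusted p = 0.414 with an estimated correlation. The chaperone genes Dnajc3 and Hyou1 rose by 1.02 ± 0.10 and 1.02 ± 0.20, and Ssr3 was at 0.10 ± 0.06 (adjusted p = 0.206). The intact pools of Il6 and Shcbp1 lay below the 25th percentile of their arrays, which leaves the size of these increases uncertain. Other genes fixed beforehand were Mmp3 (2.06 ± 0.34), which encodes stromelysin 1, Tgfb1 (0.61 ± 0.10), Vegfa (0.24 ± 0.11, adjusted p = 0.101) and Tnc (-0.09 ± 0.09, adjusted p = 0.423).

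Skeletal muscle markers were lower as a group, and 0 of 34 measured members rose, 33 fell and 1 did not pass the test (median -5.01), with 34 lower adjusted over the list alone. Skeletal muscle markers had a camera adjusted p of 4.25e-13, and adjusted p = 0.414 with an estimated correlation. The mean of this list was 12.78, 12.56 and 11.67 in the intact pools, and 7.78, 6.09 and 8.96 in the day 3 pools. Its most abundant member without a call, the actin gene Acta1, was at -4.91 ± 1.89 (adjusted p = 0.0583). In muscle development and regeneration 0 of 13 measured members rose, 9 fell and 4 did not pass the test, and 0 rose and 10 fell adjusted over the list alone (median -0.89). Skeletal muscle development and regeneration had a camera adjusted p of 5.41e-04, and adjusted p = 0.359 with an estimated correlation. Myf6 was at -4.53 ± 0.42, Myh3 at -3.95 ± 0.59 and Chrng at -0.04 ± 0.07 (adjusted p = 0.699), with the day 3 pools of Myf6 below the 25th percentile of their arrays. Beside these muscle genes, 1 of 33 measured members rose, 22 fell and 10 did not pass the test in oxidative phosphorylation and the citrate cycle, and 2 rose and 23 fell adjusted over the list alone (median -0.37). Oxidative phosphorylation and citrate cycle had a camera adjusted p of 6.37e-06, and adjusted p = 0.517 with an estimated correlation. Idh3b (-0.82 ± 0.17) and Ndufs1 (-0.75 ± 0.18) fell, and Atp5f1b was at -0.26 ± 0.12 (adjusted p = 0.0999). The mean of that list was 12.07, 11.90 and 11.54 in the intact pools, in the order of the muscle list, and 11.49, 11.46 and 11.47 at day 3, in another order. Among adipocyte markers 0 of 19 measured members rose, 15 fell and 4 did not pass the test (median -1.20), the same adjusted over the list alone. Adipocyte markers had a camera adjusted p of 1.85e-07, and adjusted p = 0.359 with an estimated correlation. Gpd1 (-2.82 ± 0.29), Plin1 (-2.36 ± 0.36) and Adipoq (-2.14 ± 0.40) fell, and Cfd was at -0.20 ± 0.20 (adjusted p = 0.44). Myofibroblast and smooth muscle markers had 1 higher and 9 lower members of 15, and 2 rose and 9 fell adjusted over the list alone (median -0.41, with the median -0.26 without day 3 pool 1). Myofibroblast and smooth muscle markers had a camera adjusted p of 0.00369, and adjusted p = 0.359 with an estimated correlation. The lower ones include Synpo2 (-3.82 ± 0.51) and Des (-2.42 ± 0.32), which skeletal muscle also expresses. Acta2, the smooth muscle actin gene, was at -0.10 ± 0.09 (adjusted p = 0.409) and Cald1 at 0.11 ± 0.08 (adjusted p = 0.288).

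Ligament and tendon fibroblast markers had 1 higher and 7 lower members of 12, the same adjusted over the list alone (median -0.47). Ligament and tendon fibroblast markers had a camera adjusted p of 0.00563, and adjusted p = 0.359 with an estimated correlation. Chad was at -2.70 ± 0.69, and at -2.00 without day 3 pool 1, Fibin at -2.18 ± 0.10, the tenomodulin gene Tnmd at -1.27 ± 0.16, the tendon transcription factor gene Scx at -0.94 ± 0.08 and Comp at -0.22 ± 0.10 (adjusted p = 0.0885). Small leucine-rich and other proteoglycans had no higher and 7 lower members of 16, also adjusted over the list alone (median -0.15). Small leucine-rich and other proteoglycans had a camera adjusted p of 0.0288, and adjusted p = 0.414 with an estimated correlation. Omd (-1.42 ± 0.09) and the fibromodulin gene Fmod (-0.63 ± 0.07) fell, and Dcn, which encodes decorin, was at -0.10 ± 0.05 (adjusted p = 0.141). The call of this list ended without day 3 pool 1 (adjusted p = 0.0743), with a median of -0.04, and the median was -0.06 without intact pool 2. Among growth factors and receptors of repair 8 of 40 measured members rose, 16 fell and 16 did not pass the test (median -0.18), the same adjusted over the list alone, with Gdf10 at -2.53 ± 0.32, Igf2 at -1.75 ± 0.36 and Inhba at -0.17 ± 0.18 (adjusted p = 0.455). Growth factors and receptors of repair had a camera adjusted p of 0.00563, and adjusted p = 0.359 with an estimated correlation. Endothelial markers had no higher and 10 lower members of 16, the same adjusted over the list alone (median -0.45). Endothelial markers had a camera adjusted p of 0.00391, and adjusted p = 0.579 with an estimated correlation. Sox17 (-1.53 ± 0.17) and Cldn5 (-0.98 ± 0.18) fell, Plvap was at -0.44 ± 0.20 (adjusted p = 0.0932), and the list's median was -0.27 without intact pool 3. The endothelial call ended with fry (adjusted p = 0.0636).

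The remaining called lists were those of nerve, mast cell and stress genes. Nerve and Schwann cell markers had 3 higher and 6 lower members of 14, the same adjusted over the list alone (median -0.22). Nerve and Schwann cell markers had a camera adjusted p of 0.0457, and adjusted p = 0.359 with an estimated correlation. Scn7a fell (-2.83 ± 0.15), Nefh rose, and Egr2 was at -0.34 ± 0.15 (adjusted p = 0.0939). The nerve call ended without day 3 pools 2 or 3, or intact pool 3 (adjusted p 0.0531 to 0.118). Mast cell markers had 2 lower members of 12, and 1 adjusted over the list alone (median -0.36), with Cpa3 at -0.75 ± 0.19, Hdc at -0.25 ± 0.08 and Tpsb2 at -0.34 ± 0.13 (adjusted p = 0.054). Mast cell markers had a camera adjusted p of 0.0457, and adjusted p = 0.523 with an estimated correlation. The mast cell call ended without day 3 pools 1, 2 or 3, or intact pool 3 (adjusted p 0.0531 to 0.0812), where the median was -0.14 without intact pool 3, and the call of Hdc ended without day 3 pools 1 or 2, or intact pools 2 or 3 (adjusted p 0.0557 to 0.0911). The nerve call also ended with the 25th percentile filter, the median filter, quantile normalization, 75th percentile centring, cyclic loess, array weights or tied genes removed (adjusted p 0.0567 to 0.144). That of the mast cell list ended with fry, quantile normalization, cyclic loess, array weights, the cartilage covariate or tied genes removed (adjusted p 0.0531 to 0.156), and that of Hdc with array weights (adjusted p = 0.0557). Over all alternatives the adjusted p of the nerve list was 6.40e-04 to 0.359 and that of the mast cell list 0.0155 to 0.523. Stress genes had 4 lower members of 14, and 3 adjusted over the list alone (median -0.45, with the median -0.22 without intact pool 3). RNA quality and stress genes had a camera adjusted p of 0.0169, and adjusted p = 0.414 with an estimated correlation. Fosb was at -1.37 ± 0.47, Hspb1 at -0.73 ± 0.07 and Fos at -0.76 ± 0.33 (adjusted p = 0.0862). The call of Fosb ended with the cartilage covariate (adjusted p = 0.0644), and without day 3 pools 1, 2 or 3, day 7 pool 2, or intact pools 2 or 3 (adjusted p 0.0528 to 0.0988), at -0.84 without intact pool 3.

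Lists that did not pass the test at day 3 were fibrillar collagens (adjusted p = 0.926), other collagens (adjusted p = 0.066), collagen processing and cross-linking (adjusted p = 0.086), matricellular and adhesive glycoproteins (adjusted p = 0.086), elastic fibre genes (adjusted p = 0.386), matrix-degrading proteases and their inhibitors (adjusted p = 0.0731), blood vessel growth (adjusted p = 0.414) and glycolysis and hypoxia response (adjusted p = 0.222). The others were Wnt pathway (adjusted p = 0.381), integrins (adjusted p = 0.633), neutrophil markers (adjusted p = 0.328), B and plasma cell markers (adjusted p = 0.381), cartilage markers (adjusted p = 0.137), bone and osteoclast markers (adjusted p = 0.414), erythroid markers (adjusted p = 0.633) and synovial lining markers (adjusted p = 0.722). No list was called with an estimated correlation (lowest adjusted p = 0.359), and 24 of 35 were called by fry, which does not compare a list with other genes. With the muscle list mean of each pool as a covariate, chosen after seeing the data, 2058 genes were called. That mean did not overlap between intact and injured pools, so the covariate is tied to the grouping. The count therefore does not measure the part of muscle content. Ckm was at 2.09 with that covariate, but it is a member of the list that makes up the covariate, whose members lie around 0 by construction.

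**Figure D1:**
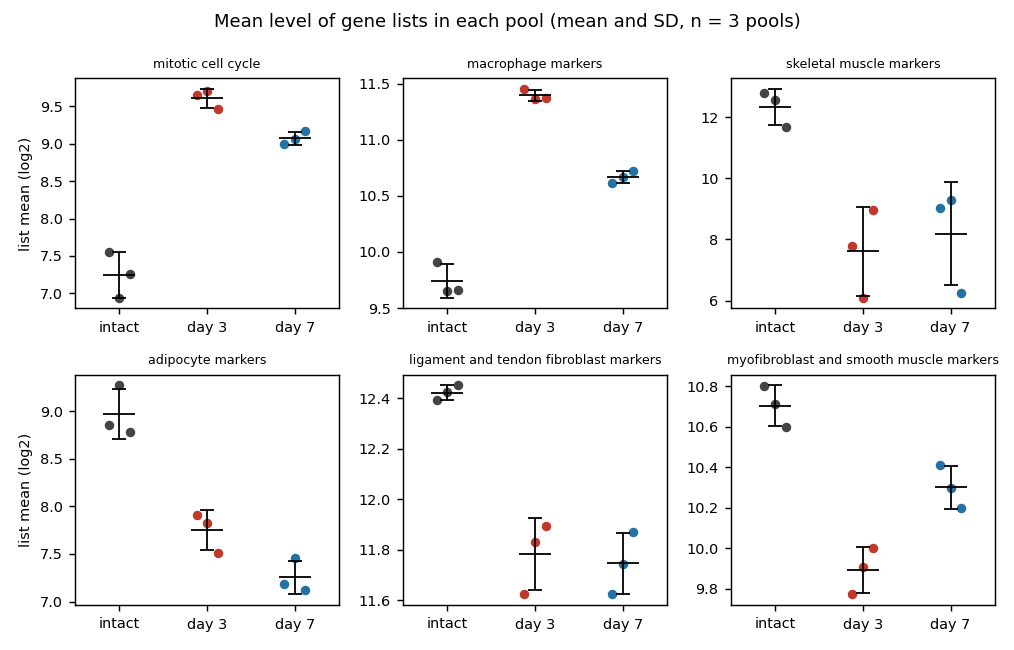
Mean log2 level of 6 gene lists (y axes, own range in each panel) in the pools of the intact, day 3 and day 7 groups (x axes); points are pools, bars the mean ± SD of 3 pools. The skeletal muscle list spans 6.09 to 8.96 in the day 3 pools and 6.25 to 9.29 in the day 7 pools.

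The second comparison set the ligament 7 days after transection against the intact ligament. Prss35, a gene of the serine protease family, rose by 4.76 ± 0.74, and the metalloproteinase genes Mmp13 (3.88 ± 0.77), Mmp11 (3.79 ± 0.33) and Mmp9 (3.71 ± 1.13) rose with it. Without intact pool 2 Prss35 was at 3.78 and Mmp13 at 2.74, and without intact pool 1 at 5.67 and 4.50. All 45 mitotic genes and 18 of 21 macrophage markers were again higher than in intact ligament. Of the muscle markers 31 of 34 fell, and of the adipocyte markers 15 of 19. With an estimated correlation these 4 lists were at adjusted p = 0.435, 0.435, 0.464 and 0.435. Acta2 (0.64 ± 0.09) and Col3a1 (0.18 ± 0.05) were above intact at day 7. The call of Mmp9 ended without day 7 pools 1, 2 or 3, or intact pools 1 or 2 (adjusted p 0.0518 to 0.071), at 2.45 without intact pool 2, and Mmp9 was at 4.86 without intact pool 3.

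Of 14217 genes, 6478 were called (limma with Benjamini-Hochberg adjustment), 3897 higher and 2581 lower, and 1208 differed at least 2-fold, 526 higher and 682 lower. The share of higher calls was 60.2%, 50.6% with cyclic loess, and 97.7% (13275 higher, 309 lower) with spike-in scaling. Pools did not overlap in 7611 genes (53.5%), where chance gives 10%. The other largest increases were in the complement regulator gene Cfi (3.98 ± 0.52) and in Kcnj15 (3.84 ± 0.52), at 4.71 and 4.60 without intact pool 1. The largest decreases were in Ckmt2 (-5.41 ± 1.00), the water channel gene Aqp4 (-5.33 ± 0.32), Myh7 (-5.33 ± 1.05), Hjv (-5.32 ± 0.92), Myh2 (-5.16 ± 1.66) and Trdn (-5.06 ± 1.08). Without day 7 pool 3 Ckmt2 was at -4.39, Myh7 at -4.63, Hjv at -4.34 and Trdn at -3.72. Aqp4 stood at 3.35 to 3.81 in the day 7 pools, below the 25th percentile of each array and not shown to be above background, so the size and rank of its decrease are uncertain. Without day 7 pool 2 Ckmt2 was at -6.12, Myh7 at -6.04, Myh2 at -6.19 and Trdn at -5.78, and without day 7 pool 1 Myh2 was at -5.93 and Trdn at -5.67. The call of Myh2 ended without day 7 pool 3, or intact pools 1 or 2 (adjusted p 0.0748 to 0.0807), at -3.35 without day 7 pool 3, and with array weights or a replicate block (adjusted p 0.0526 to 0.0706).

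In the protease list 18 of 30 measured members rose, 2 fell and 10 did not pass the test, with 19 rising and 2 falling adjusted over the list alone (median 0.46). Matrix-degrading proteases and their inhibitors had a camera adjusted p of 0.00306, and adjusted p = 0.435 with an estimated correlation. Ctsl was at 0.12 ± 0.05 (adjusted p = 0.114) and Mmp3 at 0.76 ± 0.34 (adjusted p = 0.0971). Collagen processing and cross-linking had 15 higher and 1 lower member of 23, the same adjusted over the list alone (median 0.38). Collagen processing and cross-linking had a camera adjusted p of 0.00282, and adjusted p = 0.464 with an estimated correlation. The prolyl hydroxylase genes P4ha3 (1.87 ± 0.16) and P3h1 (0.90 ± 0.08) rose, and Pcolce was at -0.05 ± 0.07 (adjusted p = 0.612). In the secretory pathway and unfolded protein response 20 of 29 measured members rose, 4 fell and 5 did not pass the test, and 21 rose and 4 fell adjusted over the list alone (median 0.40), with Hyou1 at 0.97 ± 0.20, Sdf2l1 at 0.82 ± 0.08 and Ssr3 at 0.03 ± 0.06 (adjusted p = 0.749). Secretory pathway and unfolded protein response had a camera adjusted p of 0.00319, and adjusted p = 0.464 with an estimated correlation. Col1a1 (-0.01 ± 0.05, adjusted p = 0.855) and Col1a2 (-0.01 ± 0.05, adjusted p = 0.933) did not pass the test, and the call of Col3a1 ended with cyclic loess (0.07, adjusted p = 0.272, and 8.32e-04 to 0.272 over all alternatives).

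Mitotic genes kept a median of 1.94 above intact, and 45 of 45 measured members rose, 0 fell and 0 did not pass the test, also adjusted over the list alone (camera adjusted p = 2.65e-20, and adjusted p = 0.435 with an estimated correlation). Ccna2 rose by 2.83 ± 0.30, Cdk1 by 2.59 ± 0.24 and Mki67 by 2.49 ± 0.28. Macrophage markers had 18 higher and 1 lower member of 21, the same adjusted over the list alone (median 0.86), with Ms4a7 at 1.76 ± 0.21, Arg1 at 1.73 ± 0.16, Cd68 at 1.71 ± 0.12 and Cd14 at 0.04 ± 0.13 (adjusted p = 0.842). Macrophage markers had a camera adjusted p of 1.04e-06, and adjusted p = 0.435 with an estimated correlation. For antigen presentation 8 of 10 measured members rose, 0 fell and 2 did not pass the test, with 9 rising adjusted over the list alone (median 0.58). Antigen presentation by MHC class II had a camera adjusted p of 0.00389, and adjusted p = 0.464 with an estimated correlation. RT1-DMa was at 0.78 ± 0.10, RT1-DMb at 0.73 ± 0.08 and Ctss at 0.13 ± 0.08 (adjusted p = 0.216). T and natural killer cell markers had 10 higher members of 17, the same adjusted over the list alone (median 0.31), with Cd4 at 1.41 ± 0.13, Thy1, which fibroblasts also express, at 0.91 ± 0.13 and Zap70 at 0.01 ± 0.07 (adjusted p = 0.954). T and natural killer cell markers had a camera adjusted p of 0.00667, and adjusted p = 0.435 with an estimated correlation. Il6 was at 0.99 ± 0.15, from intact pools below the 25th percentile of their arrays, Il1b at 0.49 ± 0.19 (adjusted p = 0.0657), Tgfb1 at 0.51 ± 0.10 and Vegfa at 0.27 ± 0.11 (adjusted p = 0.0745).

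Skeletal muscle markers had 31 lower members of 34, and 33 adjusted over the list alone (median -4.27), with Acta1 at -3.98 ± 1.89 (adjusted p = 0.119). Skeletal muscle markers had a camera adjusted p of 4.58e-12, and adjusted p = 0.464 with an estimated correlation. The list's mean was 9.03, 9.29 and 6.25 in the day 7 pools. In muscle development and regeneration 1 of 13 measured members rose, 7 fell and 5 did not pass the test, also adjusted over the list alone (median -0.60). Skeletal muscle development and regeneration had a camera adjusted p of 0.00552, and adjusted p = 0.464 with an estimated correlation. The call of that list ended with the median filter, every probe set tested or the muscle covariate (adjusted p 0.0791 to 0.111). Myh3 (-4.47 ± 0.59) and Myf6 (-4.30 ± 0.42) fell, with the day 7 pools of Myf6 below the 25th percentile of their arrays. Ncam1 was at -0.07 ± 0.08 (adjusted p = 0.495), and another of its probe sets was called the opposite way. Beside the muscle genes, 1 of 33 measured members rose, 26 fell and 6 did not pass the test in oxidative phosphorylation and the citrate cycle, and 1 rose and 30 fell adjusted over the list alone (median -0.43), with Idh3b at -0.84 ± 0.17, Atp5f1c at -0.84 ± 0.15 and Atp5f1b at -0.31 ± 0.12 (adjusted p = 0.0609). Oxidative phosphorylation and citrate cycle had a camera adjusted p of 1.71e-07, and adjusted p = 0.523 with an estimated correlation. The mean of that list was 11.39 in each day 7 pool, where the muscle mean varied. Adipocyte markers had 15 lower members of 19, the same adjusted over the list alone (median -1.47). Adipocyte markers had a camera adjusted p of 1.69e-09, and adjusted p = 0.435 with an estimated correlation. Adipoq (-3.34 ± 0.40) and Gpd1 (-3.22 ± 0.29) fell, and Lipe was at -0.11 ± 0.08 (adjusted p = 0.283).

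Ligament and tendon fibroblast markers had 3 higher and 7 lower members of 12, and 3 rose and 9 fell adjusted over the list alone (median -0.50). Ligament and tendon fibroblast markers had a camera adjusted p of 0.0221, and adjusted p = 0.435 with an estimated correlation. Chad was at -4.54 ± 0.69, and at -3.82 without day 7 pool 1, Clec3b at -0.99 ± 0.31, Tnmd at -0.90 ± 0.16, Scx at 0.30 ± 0.08 and Thbs4 at -0.14 ± 0.05 (adjusted p = 0.055). The call of this list ended with every probe set tested (adjusted p = 0.111). Fmod (-0.84 ± 0.07) and Dcn (-0.19 ± 0.05) fell, and Tnc was at 0.25 ± 0.09. The call of Clec3b ended without day 7 pools 1 or 2, or intact pool 1 (adjusted p 0.0865 to 0.0984), that of Scx without day 7 pool 2 (adjusted p = 0.0538) and that of Dcn without day 7 pool 2 (adjusted p = 0.0605). The call of Tnc ended without day 3 pools 1, 2 or 3, day 7 pools 2 or 3, or intact pools 2 or 3 (adjusted p 0.0518 to 0.139) and under all 4 other scalings, with adjusted p from 0.0524 to 0.182 there. It also ended with array weights, only the 6 arrays compared, a replicate block or the cartilage covariate (adjusted p 0.0664 to 0.0811), with adjusted p 0.0242 to 0.808 over all alternatives. Among growth factors and receptors 10 of 40 measured members rose, 19 fell and 11 did not pass the test, and 12 rose and 20 fell adjusted over the list alone (median -0.21), with Gdf10 at -3.69 ± 0.32, Bmp4 at -1.86 ± 0.11 and Hbegf at 0.32 ± 0.12 (adjusted p = 0.0666). Growth factors and receptors of repair had a camera adjusted p of 0.00901, and adjusted p = 0.435 with an estimated correlation. Endothelial markers had no higher and 10 lower members of 16, the same adjusted over the list alone (median -0.51), with Cldn5 at -0.91 ± 0.18, Sox17 at -0.87 ± 0.17 and Kdr at 0.13 ± 0.15 (adjusted p = 0.515). Endothelial markers had a camera adjusted p of 0.00319, and adjusted p = 0.689 with an estimated correlation. Stress genes had 8 lower members of 14, the same adjusted over the list alone (median -0.64), with Fosb at -1.78 ± 0.47, Fos at -1.19 ± 0.33, which was -0.79 without intact pool 3, and Jun at -0.15 ± 0.19 (adjusted p = 0.552). RNA quality and stress genes had a camera adjusted p of 0.00353, and adjusted p = 0.464 with an estimated correlation.

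Nerve and Schwann cell markers had 2 higher and 4 lower members of 14, the same adjusted over the list alone (median -0.15). Nerve and Schwann cell markers had a camera adjusted p of 0.0355, and adjusted p = 0.435 with an estimated correlation. Scn7a fell (-3.80 ± 0.15), Nefh rose (3.57 ± 0.55) and Egr2 was at -0.40 ± 0.15 (adjusted p = 0.0582). Nefh was at 4.22 without intact pool 1 and at 2.94 without intact pool 3. The call of this list ended without intact pool 3 (adjusted p = 0.121) and with the median filter, cyclic loess or tied genes removed (adjusted p 0.068 to 0.133), and its median was -0.26 without day 7 pool 3. Mast cell markers had 1 higher and 4 lower members of 12, the same adjusted over the list alone (median -0.39), with Cma1 at -1.27 ± 0.28, Cpa3 at -1.24 ± 0.19 and Tpsb2 at -0.19 ± 0.13 (adjusted p = 0.275). Mast cell markers had a camera adjusted p of 0.0464, and adjusted p = 0.647 with an estimated correlation. The mast cell call ended without day 3 pools 1 or 3, day 7 pool 1, or intact pool 3 (adjusted p 0.05 to 0.0779), with a median of -0.15 without intact pool 3. It also ended with cyclic loess, an intensity trend, array weights, only the 6 arrays compared, the cartilage covariate or tied genes removed (adjusted p 0.0526 to 0.133). Over all alternatives the adjusted p of the nerve list was 4.80e-04 to 0.435 and that of the mast cell list 0.0184 to 0.647. Lists that did not pass the test at day 7 were fibrillar collagens (adjusted p = 0.32), other collagens (adjusted p = 0.748), small leucine-rich and other proteoglycans (adjusted p = 0.509), matricellular and adhesive glycoproteins (adjusted p = 0.748), elastic fibre genes (adjusted p = 0.599), inflammatory cytokines, chemokines and mediators (adjusted p = 0.745), complement (adjusted p = 0.452), blood vessel growth (adjusted p = 0.928) and glycolysis and hypoxia response (adjusted p = 0.577). The others were Wnt pathway (adjusted p = 0.491), integrins (adjusted p = 0.748), myofibroblast and smooth muscle markers (adjusted p = 0.491), neutrophil markers (adjusted p = 0.452), B and plasma cell markers (adjusted p = 0.663), cartilage markers (adjusted p = 0.233), bone and osteoclast markers (adjusted p = 0.745), erythroid markers (adjusted p = 0.491) and synovial lining markers (adjusted p = 0.745). No list was called with an estimated correlation (lowest adjusted p = 0.435), and 25 were called by fry. With the muscle list mean as a covariate 2511 genes were called. The muscle list (-0.56, adjusted p = 0.0776, and 3.64e-19 to 0.464 over all alternatives) and its member Myh2 (2.42) are then adjusted for the list's own mean, which moves them by construction. Under that covariate 46 calls of named genes over the 3 comparisons ended. Of these 46 genes and comparisons 31 kept a log2 change within 1.5 times of the one above, as Mmp13 at day 3 (3.96). Another 13 were smaller, 9 of them of genes expressed in muscle, and the others Mmp9 (1.96) and Tnc (0.07) at day 7 and Gdf10 (-1.66) and Hdc (-0.09) at day 3. Chad (-4.05) and Cpa3 (-1.28) at day 3 were larger.

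Both comparisons with intact ligament used the same 3 intact pools. They shared 5074 calls in the same direction, 3120 higher and 1954 lower, and 57 calls were opposite. Independent lists of these sizes would share 1184 and 473, and simulated unchanged groups against common intact arrays shared on average 0. These had at most 2 calls in a comparison, so the simulated count does not measure what the shared controls add. The correlation of log2 changes across genes, which are not independent replicates, was 0.903 against 0.494 simulated, and the covariance was 0.437 against 0.00869. A split of the 3 intact pools would leave 1 of them in one part and was not run, and part of the excess over independent lists may come from the shared controls.

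The third comparison, of day 7 with day 3, asked which genes changed between the early times and is also the test of the difference between the 2 comparisons with intact ligament. The elastic fibre gene Fbn2 (2.41 ± 0.21), the collagen gene Col8a2 (1.27 ± 0.09), Scx (1.24 ± 0.08) and Acta2 (0.74 ± 0.09) were higher at day 7. Il6 (-1.53 ± 0.15) was lower at day 7, as were 18 of 21 macrophage markers, 22 of 45 mitotic genes and 4 of 10 MHC class II genes. With an estimated correlation these 3 lists were at adjusted p = 0.485, 0.564 and 0.534. Of 14217 genes, 2423 were called (limma with Benjamini-Hochberg adjustment), 796 higher and 1627 lower at day 7, and 194 differed at least 2-fold, 91 higher and 103 lower. The share of higher calls was 32.9%, 46.5% with 75th percentile centring, and 90.8% (784 higher, 79 lower) with spike-in scaling, so which direction holds more calls depends on the scaling. Pools did not overlap in 6092 genes (42.9%), where chance gives 10%. The count was 1357 without day 3 pool 1, 1379 without day 3 pool 2, 1356 without day 7 pool 1 and 1204 without day 7 pool 2.

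The largest increases were in Mmp9 (4.12 ± 1.13), Pamr1 (3.23 ± 0.27), Prss35 (3.13 ± 0.74), Mmp11 (3.10 ± 0.33), Gas2 (2.78 ± 0.26) and Podnl1 (2.49 ± 0.44). The largest decreases were in the osteocalcin gene Bglap (-3.67 ± 0.91), the protease inhibitor gene Serpina3n (-2.53 ± 0.20), the metallothionein gene Mt2A (-2.20 ± 0.12), Coch (-2.01 ± 0.54), Olr1 (-1.99 ± 0.30) and Pla2g2a (-1.90 ± 0.26). Of these 12 calls 4 ended when 1 pool was left out. The fit shares each gene's spread over all 9 arrays, and intact pools varied most (median SD 0.113, 0.077 at day 3, 0.078 at day 7). Prss35 stayed at 3.01 to 3.22 without any single day 3 or day 7 pool. Over all alternatives adjusted p was 0.00573 to 0.124 for Mmp9 and 2.56e-04 to 0.0773 for Prss35. It was 0.00199 to 0.0938 for Bglap and 0.00757 to 0.116 for Coch. Mmp9 lost its call without day 3 pools 1 or 3, day 7 pools 1, 2 or 3, or intact pool 1 (adjusted p 0.0513 to 0.124), Prss35 without day 3 pools 1, 2 or 3, or day 7 pools 1, 2 or 3 (adjusted p 0.0503 to 0.0773), Bglap without day 3 pools 2 or 3, or day 7 pools 1, 2 or 3 (adjusted p 0.0519 to 0.0938) and Coch without day 3 pools 2 or 3, or day 7 pools 1, 2 or 3 (adjusted p 0.0577 to 0.116). The call of Coch also ended with only the 6 arrays compared or the muscle covariate (adjusted p 0.0549 to 0.0566). Its day 7 pools, at 3.96 to 4.93, lay below the 25th percentile of their arrays, so the size and rank of its decrease are uncertain. Without day 3 pool 1 Mmp9 was at 3.40, Bglap at -4.90 and Coch at -2.61. Mmp9 was at 4.98 and Coch at -1.34 without day 3 pool 2, and Bglap at -2.79 without day 3 pool 3. Bglap stood at 6.17, 9.33 and 10.39 in the 3 day 3 pools, and the bone and osteoclast list mean at 6.69, 8.53 and 7.93 in the same pools.

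Of the macrophage markers 0 of 21 measured members rose, 18 fell and 3 did not pass the test, with 19 lower adjusted over the list alone (median -0.67). Macrophage markers had a camera adjusted p of 1.15e-12, and adjusted p = 0.485 with an estimated correlation. Cd163 was at -1.70 ± 0.17, Fcgr1a at -1.21 ± 0.12, Lgals3 at -0.16 ± 0.10 (adjusted p = 0.303) and Cd68 at -0.35 ± 0.12 (adjusted p = 0.0737). Of the mitotic genes 0 of 45 measured members rose, 22 fell and 23 did not pass the test, with 40 lower adjusted over the list alone (median -0.55). Mitotic cell cycle had a camera adjusted p of 1.15e-12, and adjusted p = 0.564 with an estimated correlation. The kinesin gene Kif11 was at -0.77 ± 0.18, the checkpoint gene Mad2l1 at -0.73 ± 0.17, Cdkn3 at -0.70 ± 0.24 (adjusted p = 0.0763) and Mki67 at -0.59 ± 0.28 (adjusted p = 0.188). The calls of these mitotic genes ended without single pools, Kif11 without day 3 pools 1 or 2, or day 7 pools 1 or 2 (adjusted p 0.0657 to 0.0752) and Mad2l1 without day 3 pools 1 or 2, or day 7 pools 1 or 2 (adjusted p 0.066 to 0.0691). MHC class II genes had 4 lower members of 10, and 7 adjusted over the list alone (median -0.38), with RT1-DMa at -0.86 ± 0.10, RT1-DMb at -0.85 ± 0.08 and Cd74 at -0.21 ± 0.10 (adjusted p = 0.18). Antigen presentation by MHC class II had a camera adjusted p of 4.01e-04, and adjusted p = 0.534 with an estimated correlation. Complement had 8 lower members of 15, and 1 rose and 9 fell adjusted over the list alone (median -0.40), with C6 at -1.22 ± 0.22, Cfd at -1.21 ± 0.20 and C1s at 0.07 ± 0.05 (adjusted p = 0.377). Complement had a camera adjusted p of 0.00837, and adjusted p = 0.534 with an estimated correlation. The inflammatory list had 2 higher and 12 lower members of 39, and 3 rose and 14 fell adjusted over the list alone (median -0.22). Inflammatory cytokines, chemokines and mediators had a camera adjusted p of 0.0257, and adjusted p = 0.534 with an estimated correlation. Ccl9 rose (1.93 ± 0.29), Ccl20 fell (-1.60 ± 0.23), Cxcl12 was at -0.29 ± 0.13 (adjusted p = 0.148) and Il1b at -0.57 ± 0.19 (adjusted p = 0.0768). The list's call ended without day 3 pool 1 (adjusted p = 0.0531), and its median was -0.15 without day 3 pool 3 and -0.14 without day 7 pool 3. Glycolysis and the hypoxia response had 8 lower members of 20, and 10 adjusted over the list alone (median -0.31), with Egln3 at -1.39 ± 0.24, the lactate transporter gene Slc16a3 at -0.95 ± 0.23 and Aldoa at -0.08 ± 0.11 (adjusted p = 0.659). Glycolysis and hypoxia response had a camera adjusted p of 0.00122, and adjusted p = 0.534 with an estimated correlation. Slc16a3 lost its call without day 3 pools 1 or 2, or day 7 pools 1 or 2 (adjusted p 0.0657 to 0.0875). Adipocyte markers had 4 lower members of 19, and 7 adjusted over the list alone (median -0.51), with Cidea at -0.95 ± 0.10, Fabp4 at -0.41 ± 0.13 (adjusted p = 0.0587) and Adipoq at -1.20 ± 0.40 (adjusted p = 0.0729). Adipocyte markers had a camera adjusted p of 0.0115, and adjusted p = 0.693 with an estimated correlation. The adipocyte call ended without day 3 pool 1 (adjusted p = 0.0531).

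Fibrillar collagens had 4 higher and no lower members of 11, also adjusted over the list alone (median 0.06). Fibrillar collagens had a camera adjusted p of 0.00837, and adjusted p = 0.534 with an estimated correlation. Col24a1 was at 1.36 ± 0.31, Col11a1 at 1.02 ± 0.12, Col1a1 at 0.05 ± 0.05 (adjusted p = 0.5), Col1a2 at 0.04 ± 0.05 (adjusted p = 0.607) and Col3a1 at 0.06 ± 0.05 (adjusted p = 0.441). The list's median was 0.19 without day 3 pool 2, 0.21 without day 3 pool 3 and 0.21 without day 7 pool 1, and Col24a1 lost its call without day 7 pools 1, 2 or 3 (adjusted p 0.051 to 0.0657). Other collagens had 5 higher and 2 lower members of 26, and 7 rose and 3 fell adjusted over the list alone (median 0.12), with Col8a2 higher, Col22a1 lower (-0.88 ± 0.15) and Col6a2 at 0.30 ± 0.10 (adjusted p = 0.0663). Other collagens had a camera adjusted p of 0.0277, and adjusted p = 0.693 with an estimated correlation. Their call ended without day 3 pool 1, or day 7 pool 2 (adjusted p 0.0553 to 0.132) and with fry, 75th percentile centring or tied genes removed (adjusted p 0.0688 to 0.157), with adjusted p 0.00124 to 0.693 over all alternatives, and their median was 0.24 without day 3 pool 2. Collagen processing had 4 higher members of 23, and 5 adjusted over the list alone (median 0.16), with Fkbp14 at 0.59 ± 0.09, P3h4 at 0.53 ± 0.10 and Serpinh1 at 0.16 ± 0.06 (adjusted p = 0.121). Collagen processing and cross-linking had a camera adjusted p of 0.00122, and adjusted p = 0.534 with an estimated correlation. Matricellular and adhesive glycoproteins had 7 higher and 1 lower member of 21, and 8 rose and 2 fell adjusted over the list alone (median 0.12, with the median 0.20 without day 3 pool 3). Matricellular and adhesive glycoproteins had a camera adjusted p of 0.00132, and adjusted p = 0.485 with an estimated correlation. Cthrc1 was at 1.06 ± 0.27, Fndc1 at 0.86 ± 0.09, Tnc at 0.34 ± 0.09 and Sparc at 0.11 ± 0.05 (adjusted p = 0.194). Cthrc1 lost its call without day 3 pools 1, 2 or 3, or day 7 pools 1, 2 or 3 (adjusted p 0.0502 to 0.0907) and Tnc without day 3 pools 1, 2 or 3, or day 7 pools 2 or 3 (adjusted p 0.0635 to 0.0921). Over all alternatives the adjusted p was 7.81e-04 to 0.0907 for Cthrc1 and 0.0075 to 0.0921 for Tnc. Elastic fibre genes had 4 higher members of 16, the same adjusted over the list alone (median 0.16), with Mfap4 at 1.52 ± 0.18 beside Fbn2 and with Fbn1 at 0.01 ± 0.06 (adjusted p = 0.948). Elastic fibre genes had a camera adjusted p of 0.0257, and adjusted p = 0.693 with an estimated correlation. Their call ended without day 3 pool 1 (adjusted p = 0.0531) and with fry, 75th percentile centring, the mean of probe sets, every probe set tested or tied genes removed (adjusted p 0.0532 to 0.104), with adjusted p 0.00821 to 0.693 over all alternatives.

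Myofibroblast and smooth muscle markers had 7 higher members of 15, and 7 rose and 1 fell adjusted over the list alone (median 0.38, with the median 0.59 without day 7 pool 3). Myofibroblast and smooth muscle markers had a camera adjusted p of 6.53e-04, and adjusted p = 0.485 with an estimated correlation. Tagln rose (0.99 ± 0.13) beside Acta2, Tpm1 was at 1.02 ± 0.23 and Tpm2 at 0.16 ± 0.08 (adjusted p = 0.212). The call of Tpm1 ended without day 3 pools 1 or 2, or day 7 pools 1 or 2 (adjusted p 0.0641 to 0.0712) and with the mean of its probe sets (0.69, adjusted p = 0.262, and 0.00236 to 0.262 over all alternatives). Among genes fixed beforehand, Mmp3 fell (-1.30 ± 0.34) and lost its call without day 3 pools 1, 2 or 3, or day 7 pools 1 or 2 (adjusted p 0.0653 to 0.103). Mmp13 (-0.39 ± 0.77, adjusted p = 0.774), Fmod (-0.21 ± 0.07, adjusted p = 0.0554), Dcn (-0.09 ± 0.05, adjusted p = 0.271), Tnmd (0.37 ± 0.16, adjusted p = 0.139), Tgfb1 (-0.11 ± 0.10, adjusted p = 0.487), Vegfa (0.03 ± 0.11, adjusted p = 0.887) and Acta1 (0.93 ± 1.89, adjusted p = 0.781) did not pass the test. None of the 34 muscle markers was called (median 0.60, camera adjusted p = 0.0704). Lists that did not pass the test were small leucine-rich and other proteoglycans (adjusted p = 0.201), matrix-degrading proteases and their inhibitors (adjusted p = 0.105), growth factors and receptors of repair (adjusted p = 0.815), blood vessel growth (adjusted p = 0.145), oxidative phosphorylation and citrate cycle (adjusted p = 0.547), secretory pathway and unfolded protein response (adjusted p = 0.805), Wnt pathway (adjusted p = 0.285), integrins (adjusted p = 0.763), ligament and tendon fibroblast markers (adjusted p = 0.547), neutrophil markers (adjusted p = 0.547) and T and natural killer cell markers (adjusted p = 0.425). The others were B and plasma cell markers (adjusted p = 0.503), mast cell markers (adjusted p = 0.978), endothelial markers (adjusted p = 0.688), skeletal muscle markers (adjusted p = 0.0704), skeletal muscle development and regeneration (adjusted p = 0.0833), cartilage markers (adjusted p = 0.953), bone and osteoclast markers (adjusted p = 0.555), nerve and Schwann cell markers (adjusted p = 0.853), erythroid markers (adjusted p = 0.853), synovial lining markers (adjusted p = 0.547) and RNA quality and stress genes (adjusted p = 0.555). No list was called with an estimated correlation (lowest adjusted p = 0.485), and 14 were called by fry.

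**Figure D2:**
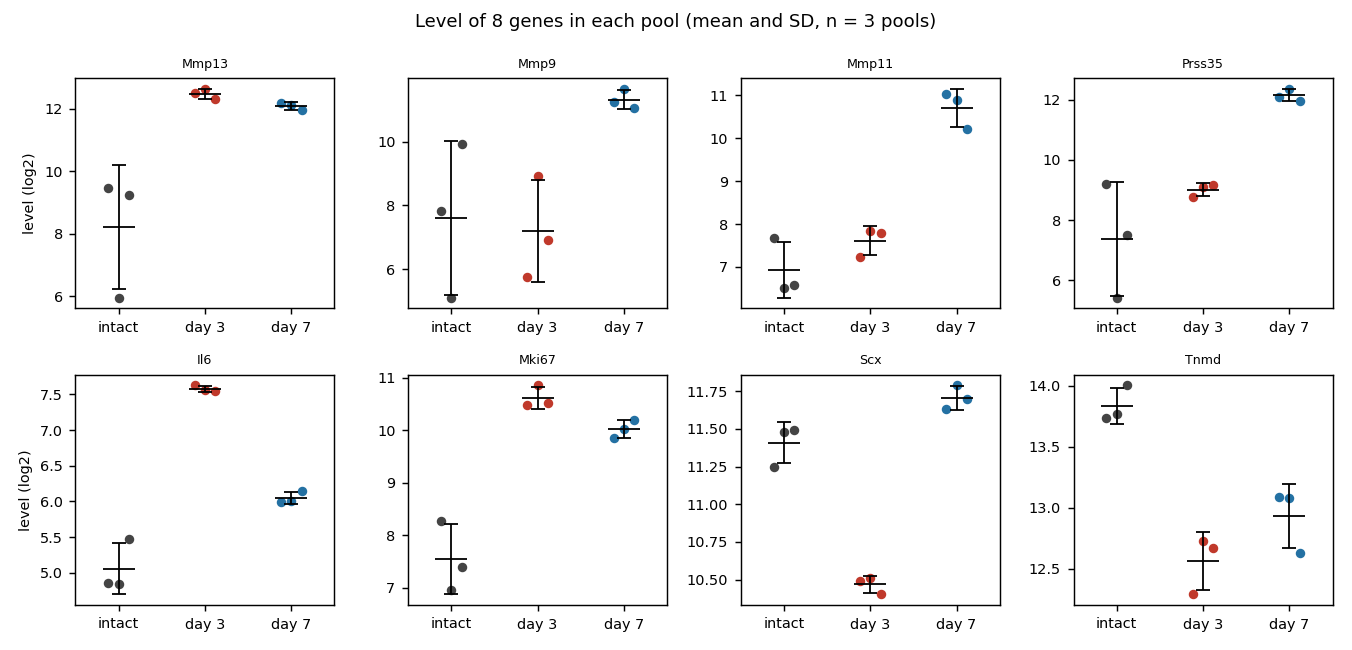
Log2 level of 8 genes named in the report (y axes, own range in each panel) in the pools of the intact, day 3 and day 7 groups (x axes); points are pools, bars the mean ± SD of 3 pools. Mmp13 has means of 12.48 at day 3 and 12.09 at day 7, while Mmp9 varies between 5.75 and 8.91 in the day 3 pools.

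Of the day 3 calls, 1393 were called the opposite way from day 3 to day 7, 1143 higher then lower and 250 lower then higher. Independent lists would give 640, and simulated unchanged groups, with at most 2 calls in a comparison, gave on average 0, which does not measure what the shared day 3 pools add. The correlation across genes of these log2 changes was -0.32 against -0.51 simulated, and their covariance -0.0697 against -0.00895. Without single pools the count was 788 (day 3 pool 1), 817 (day 3 pool 2), 793 (day 7 pool 1) and 704 (day 7 pool 2).

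**Figure D3:**
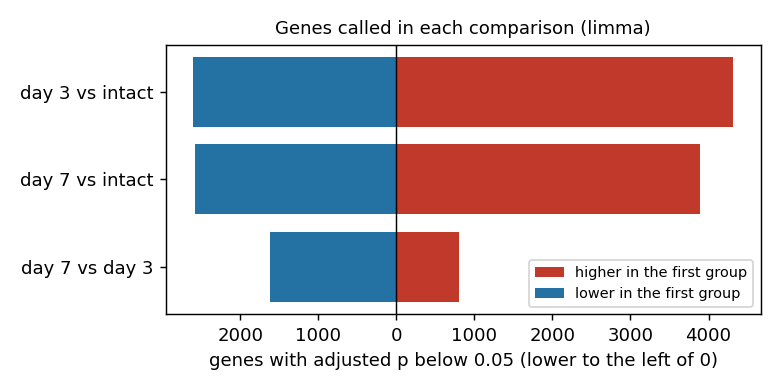
Number of genes with an adjusted p below 0.05 (x axis) in each comparison (y axis), with genes higher in the first-named group to the right of 0 and lower ones to the left. There are 4320 higher and 2607 lower genes at day 3, and 796 and 1627 between the days.

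Control transcripts added to each sample also differed between groups. The 24 poly-A spike-in probe sets, which report RNAs added before labelling, had a median difference of -1.07 at day 3 and -1.38 at day 7 against intact (exact permutation test, two-sided p = 0.1 for each, the smallest that 3 pools against 3 allow). The 18 hybridization control probe sets differed by -0.12 (exact permutation test, two-sided p = 0.3) and -0.29 (p = 0.1). If arrays were scaled to the spike-in probe sets, the median difference of all genes would be 0.92 at day 3 and 1.30 at day 7 against intact, and 0.35 between the days. The changes above are therefore relative to the median of each array. The beta-actin 3' minus 5' difference was 0.82 ± 0.02 (SD, n = 3) in intact pools, 0.84 ± 0.06 at day 3 and 0.77 ± 0.05 at day 7.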

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

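The tests of normalization for the muscle and mitotic lists and the other splits of the pools were chosen beforehand, and the tests of muscle amount, of a muscle response, of dilution, of normalization for the macrophage list and of the control transcripts were chosen only after the result was seen.

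Skeletal muscle markers were lower in the injured pools, 33 of 34 at day 3 (median -5.01) and 31 at day 7 (median -4.27), with adjusted p = 0.414 and 0.464 with an estimated correlation. Normalization between arrays is not in line with this, since the median against intact was at most -4.26 over 4 other scalings. Differing amounts of skeletal muscle in the pools may account for it: the within-group SD of the list mean was 1.33, the highest of 35 lists, and the next was 0.73. The SD was 1.44 at day 3 and 1.69 at day 7. In the intact pools it was 0.59, below the 0.64 of the erythroid list there. Uneven levels, mostly among the injured pools, do not by themselves account for the gap from intact. A response of muscle genes to injury was not excluded, because the lowest intact pool lay 2.38 above the highest injured pool, and tissue collected and injury cannot be told apart in this design. The oxidative phosphorylation list followed the order of the muscle list in the intact pools and not in the injured ones.

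Mitotic genes (45 of 45 at each day) and macrophage markers (21 and 18 of 21) were higher in the injured pools, with adjusted p = 0.359 at day 3 and 0.435 at day 7 for each list with an estimated correlation. Dilution by muscle and fat RNA in the intact pools would raise cell types outside that tissue alike. The endothelial list was taken as the reference: the mitotic median exceeded the endothelial one by at least 2.45 and the macrophage median by at least 1.37. The endothelial list fell at day 3 and day 7, as the muscle and adipocyte lists did (camera adjusted p = 0.579 and 0.689 with an estimated correlation). Endothelial transcripts may have come with the muscle and fat, so this test cannot decide on dilution. Over 4 other scalings the mitotic median against intact was at least 1.87, above the bound of 1 set beforehand, and the macrophage median was at least 0.78. The bound of 1 does not suit the macrophage list, whose day 7 median was 0.86 under the authors' normalization, so its bound, set after its values were seen, was 0.5 times its value there. Both lists and the comparisons with intact ligament were fixed before the data were examined, so higher levels in the injured pools were tested. A biological change after injury as the cause of these levels was not tested. These values do not separate a change within cells from a change in their number.

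Poly-A spike-in probe sets, which the comparisons do not use, were lower in the injured pools, by a median of -1.07 at day 3 and -1.38 at day 7. Brightness of hybridization or scanning would move the hybridization controls as well, and their change was at most 0.208 of that of the spike-ins. The lowest intact pool lay 0.60 above the highest injured pool, which restates the pattern and tests no cause. A lower poly-A share of total RNA in the intact pools may account for it. That share cannot be told apart from a different amount of RNA per reaction, which the labels do not give. No biological explanation was tested.

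Other splits of the 6 pools of each comparison into 3 and 3 were counted. The real split gave 6927, 6478 and 2423 genes at day 3, at day 7 and between the days, and the highest other split gave 0, 1 and 0, so 1 of 10 splits had as many genes in each comparison. For gene lists the real split gave 19, 17 and 13, and the highest other split 16, 14 and 14, so 1, 1 and 2 of the 10 splits had as many lists. With 10 splits a share under 0.05 cannot be reached. Many lists were called under splits that mix the groups. Each such split keeps 2 pools of a group together, so part of the real difference remains and the rest adds to the spread. Neither the gene counts nor the list counts of these splits show what unchanged groups would give. No list was called with an estimated correlation, so the number of called lists is weak evidence by itself.

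The effects at day 3 and day 7 differed, by the direct test of day 7 against day 3, in 8 lists called in a comparison with intact ligament. With an estimated correlation none of the 8 was called (adjusted p 0.485 to 0.693), and the inflammatory and adipocyte calls ended without day 3 pool 1 (adjusted p = 0.0531 for both). Their median log2 differences, day 7 minus day 3, were collagen processing and cross-linking 0.16, mitotic cell cycle -0.55, inflammatory cytokines, chemokines and mediators -0.22, complement -0.40, antigen presentation by MHC class II -0.38, myofibroblast and smooth muscle markers 0.38, macrophage markers -0.67, adipocyte markers -0.51. Counted here are genes the report names in a comparison with intact ligament and that were called in one of these, not those it names between the days alone. Of them 22 were called lower at day 7 than at day 3, with log2 differences of Il6 -1.53, Steap1 -1.50, Il1rl1 -1.39, Clec3b -1.31, Mmp3 -1.30, Ccl7 -1.21, Cfd -1.21, Gdf10 -1.16, Inhba -1.05, Scn7a -0.97, RT1-DMa -0.86, RT1-DMb -0.85, Cd14 -0.83, Ctss -0.81, Arg1 -0.79, Mpeg1 -0.76, Cd3g -0.68, Shcbp1 -0.67, Omd -0.51, Dnajc3 -0.37, Serping1 -0.25, Ctsl -0.25. Another 10 were called higher, at Tnc 0.34, Thy1 0.51, Cald1 0.57, Sox17 0.66, Acta2 0.74, Scx 1.24, Fibin 1.58, Mmp11 3.10, Prss35 3.13, Mmp9 4.12. The calls of Mmp3, Mmp9, Prss35 and Tnc between the days ended when single pools were left out, as given in the report. This was examined for the 11 of these genes described between the days in the report, and not for the other 21. Signals also appeared in probe sets the gene comparisons leave out: of those without a gene name in the annotation table, 2688 were called at day 3 and 2574 at day 7, and of those with several gene symbols 219 and 184.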

How the results depend on the processing

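The muscle covariate, cartilage covariate, removal of tied genes, spike-in scaling and the authors' p-values were chosen after seeing the data, and the other alternatives before the data were examined. Gene counts in the order day 3 vs intact, day 7 vs intact and day 7 vs day 3 (6927, 6478 and 2423) moved by over 1.5 times as follows. Every probe set tested gave 11795, 11531 and 3967, and a 2-fold minimum 1253, 1208 and 194, both by construction. Spike-in scaling gave 12746 (97.0% higher), 13584 (97.7%) and 863 (90.8%), and no single named gene or list was tested under it. It moves all genes of an array by the same value, and the median difference of all genes became 0.92 and 1.30 against intact. Small falls would then be rises, such as the medians of the endothelial (-0.45 and -0.51), ligament (-0.47 and -0.50) and oxidative phosphorylation lists (-0.37 and -0.43). The pairwise p-values of the authors' deposited table, adjusted over the same genes, gave 3092, 2218 and 365. The muscle covariate gave 2058 and 2511 against intact, and array weights gave 4262 between the days. The muscle list mean was 11.67 to 12.78 in intact pools and 6.09 to 9.29 in injured pools. That covariate is thus tied to the grouping against intact, which widens the standard errors by construction. Its counts against intact therefore do not measure the part of muscle content. Between the days, where the ranges of its values overlap, 1903 genes were called. Shared calls (5074) were 8434, 867 and 1519 with every probe set, the 2-fold minimum and the muscle covariate. Opposite calls (1393) were 2120, 74 and 594 with array weights, the 2-fold minimum and the muscle covariate. Camera with an estimated correlation called 0 lists in each comparison, and fry 24, 25 and 14. The muscle covariate turned Ckm at day 3 (2.09) and Myh2 at day 7 (2.42), members of the list it is made of, by construction. Except where stated to be by construction, the cause was not tested.

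Leaving out single pools gave 1204 to 3130 genes between the days and 704 to 1643 opposite calls. Fewer samples are part of that construction, and the other counts stayed within 1.5 times. Under the 4 other scalings, which all bring the arrays to a common level as spike-in scaling does not, no call of a named gene or list changed direction. The filters, the mean of probe sets and the trend prior changed none either. Results without a call did change direction, 7 of genes and 4 of lists with quantile normalization, and 6 and 2 with cyclic loess. With 75th percentile centring 1 and 2 did, with the mean of probe sets 2 and 2, and with each filter 0 and 2. An offset before the log was not run, since values were already log2. Filters removed some named genes, which then have no value. Values near the arrays' ceiling and background limit what differences can be seen.

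Same-numbered pools of day 3 and of the other groups share only a number. Correlations of their deviations from the group means were 0.154, -0.179 and -0.171 (intact and day 3) and 0.146, -0.295 and -0.617 (day 3 and day 7), and not every pool correlated best with its own number. With a replicate block 6591, 6139 and 1843 genes were called. At day 7 against intact the block ended the calls of Myh2 and Tnc, as given in the report, and no other call of a named gene or list. Elsewhere it ended the calls of Fosb at day 3 and of Mmp3, Mmp9 and Tnc between the days. Adipoq, Fabp4 and Fmod between the days and other collagens at day 3 became calls.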

Other observations

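Tissue markers also varied between pools of one group. The values below describe single pools, and those of tested lists and their members also enter the comparisons above. The cartilage collagen gene Col2a1 stood at 8.88, 7.24 and 12.77 in the intact pools, 6.62, 11.71 and 11.48 in the day 3 pools and 6.08, 11.67 and 10.76 in the day 7 pools. The bone gene Ibsp stood at 5.59, 6.41 and 9.16 in the intact pools, 5.56, 11.01 and 8.87 at day 3 and 5.68, 8.79 and 7.41 at day 7. Both genes were singled out after their values were seen. The erythroid list mean was 8.22 in intact pool 3, against 7.18 and 7.06 in the other intact pools.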
